A study of Asparagus officinalis with 37 samples.

How the data were processed

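Small RNAs of garden asparagus (Asparagus officinalis), a dioecious plant with separate male and female individuals, were measured by sequencing in floral organs of rising size and in vegetative tissue. Of the 37 samples of the series, 28 had processed files. These were 24 small RNA libraries and 4 libraries of double-stranded RNA (dsRNA) treated with a ribonuclease. The other 9 samples, of messenger RNA and long single-molecule reads, were not analysed here.

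Per the labels' protocols, total RNA was isolated with a plant RNA reagent, small RNAs were size selected on a polyacrylamide gel, and libraries were made with a TruSeq small RNA kit and sequenced on a HiSeq instrument. The deposited files hold, without a header, a raw count of reads for each distinct sequence tag, and no normalisation was applied to these counts. The submitters' processing notes name Bowtie 0.12.8 without saying what it was used for. The tool and settings of adapter trimming and the genome build are not given in the sources used here. Tags spanned 18 to 34 nt in the small RNA libraries and 18 to 51 nt in the dsRNA libraries. No tag of up to 31 nt occurred more than once in a file, and longer tags were not checked for this.

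Groups were taken from sample titles and source names. They were 5 anther libraries (0.7, 1.1, 1.5, 1.8 and 2.0 mm), 5 libraries of pistils from male plants (0.5, 0.7, 1.1, 1.5 and 1.8 mm), 6 libraries of pistils from female plants (1.5, 2.0, 2.8, 3.5, 4.2 and 4.5 mm) and 3 vegetative libraries. The vegetative libraries came from cladophylls (the leaf-like branches), an old spear and the shoot of a young plant. A further 3 libraries came from whole buds and 2 from anthers given as a size range. The tissue field of the labels disagreed with the titles for the 0.7 mm anthers and for the whole buds, and the titles were used. No size was repeated, so each SD is a spread over sizes or tissues, and p-values measure only the spread among these samples, which may be partly technical. Among 42 pairs of small RNA libraries within a group, the lowest chi-square per degree of freedom was 22.7, so none of these pairs appeared to be a duplicate. Pairs across groups and pairs of dsRNA libraries were not compared.

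Depth ran from 28794913 to 53728958 reads in the small RNA libraries and from 12118739 to 20543210 reads in the dsRNA libraries. At this depth the counting error of a length share was far below the spread between libraries. Intervals for single libraries are 95% intervals, Wilson for shares and exact Poisson for read counts, and a count of 0 allows up to 3 reads. Reads carried no molecular identifiers, so intervals and limits cover counting error only.

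Conserved families were counted from 49 sequences of 31 families in 9 lists, written before the data were examined. A tag of 20 to 22 nt was assigned to a family when its first 20 nt had at most 2 mismatches to a listed sequence, so members of related families can share reads. Family levels are RPM, reads scaled to a common total over all tags of the library. Tests used the quasi-likelihood method of edgeR 4.0.16 in R 4.3.3 with the full library total as library size, a filter of 1 RPM in at least 3 libraries, and Benjamini-Hochberg adjustment at 0.05. Slopes on organ size (log2 per mm) were fitted in the same way within each organ series, and the difference between the anther and male pistil slopes was tested in a joint fit.

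Tags of 20 to 24 nt with at least 20 CPM (counts scaled in the same way) in at least 3 libraries of a comparison were tested singly with edgeR and TMM scaling. A 22-nt kit oligonucleotide was removed from the tested tags. Length shares were compared by exact two-sided permutation tests over every split of the libraries, with Benjamini-Hochberg adjustment over 6 tests.

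The text names every family past the threshold in a comparison (up to 25), and miR2275, miR482/miR2118, miR390 and tasiR-ARF whatever their values. It also names, per comparison, the 3 tags with the largest fold each way past the threshold whose libraries did not overlap between groups and whose mean reached 50 CPM in either group, leaving out tags within 2 mismatches of a listed family. That match was aligned at the first base, so variants of a listed family with a shifted start can remain among the named tags. Exact matches to 3 tRNAs and to the core of 5.8S rRNA were counted, which covers a small part of structural RNA.

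The fits were tested on simulated counts drawn from the real means and library sizes. With 200 changed tags, those changed 4-fold were recovered at 98% for anther against male pistil (14 false among 212 calls), 92% for female against male pistil (10 among 199) and 62% for reproductive against vegetative (9 among 159). With 6 changed families in each of 20 data sets, families changed 4-fold were recovered at 75%, 91.7% and 20% in the same order, with 3 false among 108 calls, 12 among 125 (9.6%) and 1 among 45. At 8-fold the family values were 100%, 96.7% and 53.3%. The low recovery in the last comparison limits what its 3 vegetative libraries can show.

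Alternatives were DESeq2 1.42.0, other filters and scalings, exact matching, size as a covariate, the series number as a block, added libraries, and each library left out in turn. Summaries used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and figures Matplotlib 3.10.9. No genome was used here, so tags carry no coordinates or gene annotation, and phased loci were not analysed here.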

Results

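The series followed small RNAs through floral organs of asparagus, with organ size as the measure of developmental stage, and asked about phased small interfering RNAs (phasiRNAs) of reproductive tissue. Anthers (n = 5), pistils of male plants (n = 5), pistils of female plants (n = 6) and vegetative tissue (n = 3) were profiled, together with 3 whole-bud libraries, 2 anther libraries of a size range and 4 ribonuclease-treated dsRNA libraries. Male flowers of asparagus carry a pistil that does not complete development. Each small RNA library held 4353104 to 10544769 distinct tags.

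In floral organs, 24-nt small RNAs, the length class of heterochromatic small interfering RNAs, took a larger share of reads than in vegetative tissue, and 21-nt small RNAs, the length of most microRNAs, a smaller one. The 24-nt class made up 30.3% ± 4.04 of reads in the reproductive libraries (SD, n = 16) and 20.4% ± 1.40 in the vegetative libraries (SD, n = 3), a difference of 9.85 points. The 21-nt class made up 15.5% ± 2.65 and 22.8% ± 1.90 in the same libraries, a difference of -7.33 points. In exact two-sided permutation tests these gave p = 0.00103, the smallest that 969 splits allow, and p = 0.00206, both with an adjusted p of 0.00619. Counted over distinct tags rather than reads, the differences were 2.35 points (exact permutation p = 0.151) and -0.65 points (exact permutation p = 0.266).

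No test of length shares passed for anthers or female pistils against male pistils, and anthers were not tested against female pistils. The 24-nt share was 30.6% ± 5.51 in anthers (SD, n = 5), 28.9% ± 3.60 in male pistils (SD, n = 5) and 31.1% ± 3.35 in female pistils (SD, n = 6). Exact permutation tests against male pistils gave p = 0.556 (adjusted 0.667) for anthers and p = 0.305 (adjusted 0.458) for female pistils. The 21-nt shares were 16.4% ± 4.35, 15.8% ± 1.75 and 14.6% ± 1.28, with exact permutation p = 0.778 (adjusted 0.778) for anthers and 0.221 (adjusted 0.442) for female pistils. Over reads of 20 to 24 nt only, the 21-nt share of female pistils differed by -2.30 points (exact permutation p = 0.0325, unadjusted). Without the 1.8 mm anthers the 21-nt difference of anthers from male pistils went from 0.629 to -0.955 points. Across the 6 female pistils the 24-nt share showed no detectable relation to size (Pearson r = -0.269, exact permutation p = 0.624; Spearman rho = -0.257, exact permutation p = 0.658), and r was -0.319 without the 2 sizes farthest from the median.

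**Figure D1:**
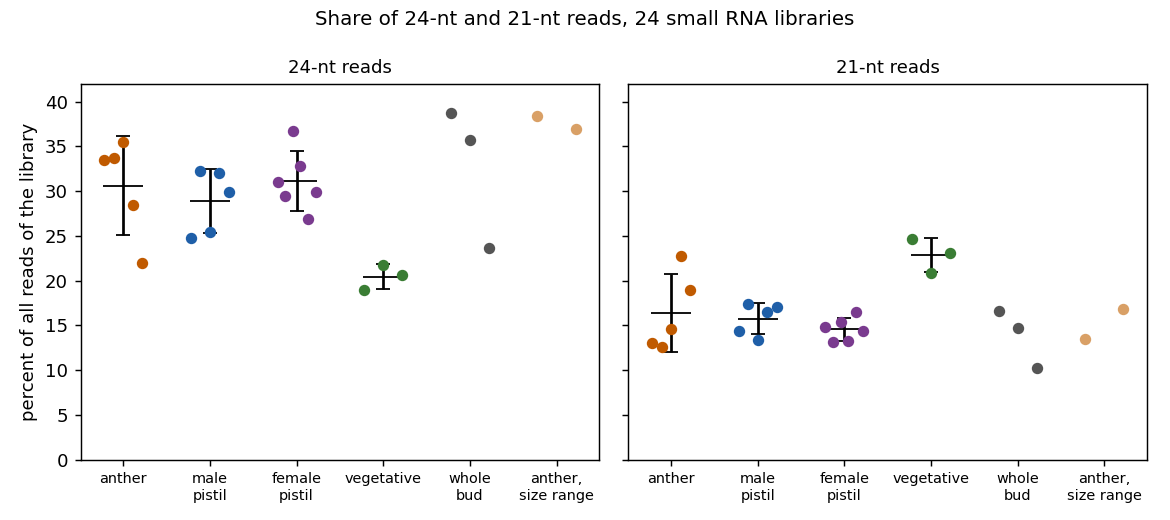
Percent of all reads of each library that are 24 nt (left) or 21 nt (right) long, by tissue, with 1 point per library and, for the 4 tissues used in tests, the mean and SD in black. The 3 vegetative libraries lie at 18.9 to 21.7% for 24 nt, below each of the 16 single-size floral libraries.

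Anthers differed strongly from the pistils of male flowers in their conserved families. Several families with roles in auxin signalling and phase change were higher in anthers: miR393, which targets auxin receptor transcripts, stood at 801 ± 195 RPM against 24 ± 10.6 RPM (SD, n = 5 each), and miR167, which targets AUXIN RESPONSE FACTOR transcripts, at 1422 ± 533 against 44.4 ± 45.3 RPM. The paired regulators of phase change rose together, miR156 by 3.77 ± 0.36 (log2 ± SE) and miR172 by 4.69 ± 0.55. miR172 was scarce in both, at 3.83 ± 1.87 RPM in anthers and 0.144 ± 0.0835 RPM in male pistils. Lower in anthers were tasiR-ARF, the trans-acting small RNA against ARF transcripts, at 11.9 ± 3.45 against 166 ± 41.3 RPM, and miR319, which targets TCP transcripts, at 42.9 ± 8.43 against 834 ± 430 RPM. Every library of each group lay beyond all libraries of the other for these 6 families.

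In edgeR, 13 of 23 tested families passed the threshold, 7 higher and 6 lower in anthers. The phase and flower list had 4 of 5 tested families past the threshold: miR156 and miR172 rose, and miR319 (log2 -4.28 ± 0.45, adjusted p = 6.33e-07) and miR159 (log2 -2.46 ± 0.46, adjusted p = 0.00022) fell. All 3 auxin families changed, miR393 upward (log2 5.06 ± 0.44, adjusted p = 1.7e-07), miR167 upward (log2 5.00 ± 0.79, adjusted p = 7.89e-05) and miR160 downward (log2 -1.73 ± 0.40, adjusted p = 0.00136). In the tasiRNA list, tasiR-ARF fell (log2 -3.81 ± 0.35, adjusted p = 2.21e-07), while its trigger miR390 had a log2 difference of -0.95 ± 0.67 (adjusted p = 0.254) and passed only without the 1.8 mm male pistils (-1.22, adjusted p = 0.0425). Of 5 tested organ and meristem families, miR169 (2.88 ± 0.63, adjusted p = 0.000955) and miR396 (1.81 ± 0.57, adjusted p = 0.0108) rose. Of 4 tested nutrient and stress families, miR827 fell (-4.24 ± 0.76, adjusted p = 0.000171). The only tested family of the monocot list, miR5179, also fell (-3.81 ± 0.99, adjusted p = 0.00341), and miR168, the tested family of the silencing machinery list, did not pass (-0.54 ± 0.47, adjusted p = 0.356). Adjusted over the list alone, the count of calls in each list was that given here. miR403, the eudicot control, stayed below the filter in all 3 group comparisons. For miR396 the direction depended on matching, with a log2 difference of -0.02 when the first 20 nt had to match exactly, and its call was lost with the 2 size-range anther libraries added (log2 1.40, adjusted p = 0.101) and with the 0.5 to 1.0 mm library alone (log2 1.58, adjusted p = 0.0576). The call of miR827 was lost with the same addition (log2 -2.16, adjusted p = 0.0821) but not with the 0.5 to 1.0 mm library alone, and miR827 stood at 9.07 RPM in the library labelled 1.0 to 1.5 mm and 0.389 RPM in the other.

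miR2275, which sets off production of 24-nt phasiRNAs in grasses, was higher in anthers than in male pistils (log2 6.36 ± 1.50, adjusted p = 0.0018), and 3 of the 5 anther libraries lay above every male pistil library. It reached 12.2, 10.3 and 8.72 RPM (544, 528 and 375 reads) in anthers of 0.7, 1.1 and 1.5 mm, and 0.0744 and 0.0329 RPM (4 reads and 1 read) in anthers of 1.8 and 2.0 mm. The 5 male pistil libraries each held 0 to 6 reads. The family fell below the filter, and so was not tested, without any 1 of the 0.7, 1.1 or 1.5 mm anthers and with exact matching, since its main tag TTCGGTTTCCTCCAACATCTCA has 2 mismatches to the listed sequences. miR482/miR2118, the trigger family of 21-nt phasiRNAs in grasses, was at 42.4 ± 9.29 RPM in anthers and 33.3 ± 31.5 RPM in male pistils (log2 0.35 ± 0.57, adjusted p = 0.572). In this list 1 of 2 families passed, also when adjusted over the list alone.

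Among 3569 abundant tags, 993 differed between anthers and male pistils, 531 higher and 462 lower in anthers. The 24-nt tags numbered 243 higher and 156 lower of 1222, and the 21-nt tags 124 higher and 123 lower of 821. The 21-nt tag TACATGTCTCAAATCACCCGG was at 104 ± 127 CPM in anthers and 0.367 ± 0.212 CPM in male pistils (log2 8.59 ± 1.31). TCATTAAACAACTTGAACGCC (log2 6.72 ± 0.93) and GCCGGCCGGGGGACGGACTGGGA (log2 5.22 ± 1.05) were also higher. Lower in anthers were TGTCGTGACCGATTGAGACGG, at 0.857 ± 0.614 against 90.6 ± 73.8 CPM (log2 -6.56 ± 0.83), CACTTGTCGTGACCGATTGAG (log2 -6.06 ± 0.88) and CCGCCCGGACGCGATGTACAG (log2 -5.83 ± 0.65). Without TMM scaling, which moved the median tag by -0.187 on the log2 scale, the split was 353 higher and 543 lower. The count fell to 590 without the 1.1 mm male pistils and to 646 without the 1.5 mm male pistils, and was 4340 with a filter of 5 CPM.

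Between pistils of female and male flowers the lowest adjusted p belonged to miR393 and miR535. miR393 was at 105 ± 53.6 RPM in female pistils (SD, n = 6) and 24 ± 10.6 RPM in male pistils (SD, n = 5), and miR535 at 17.6 ± 5.65 against 7.52 ± 1.59 RPM, with all 6 female libraries above every male library for both. miR319 was lower in female pistils, at 344 ± 93.1 against 834 ± 430 RPM, as were tasiR-ARF, at 91.3 ± 13.0 against 166 ± 41.3 RPM, and miR398, which targets copper superoxide dismutase transcripts, at 0.569 ± 0.418 against 2.95 ± 3.50 RPM. miR156 was at 17.2 ± 3.76 against 8.26 ± 3.41 RPM. The sizes of the 2 series overlapped little, so organ size differed along with sex.

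In edgeR, 6 of 21 tested families passed, 3 higher and 3 lower in female pistils. In the phase and flower list, 3 of 4 changed, miR535 (log2 1.23 ± 0.32, adjusted p = 0.0155) and miR156 (1.06 ± 0.33, adjusted p = 0.0312) upward and miR319 (-1.28 ± 0.36, adjusted p = 0.0213) downward. miR393 rose (2.13 ± 0.43, adjusted p = 0.00358) among 3 auxin families, with 2 passing when adjusted over the list alone. In the tasiRNA list, tasiR-ARF fell (-0.87 ± 0.29, adjusted p = 0.0368) and miR390 had a log2 difference of -0.50 ± 0.60 (adjusted p = 0.46). Of 4 nutrient and stress families miR398 fell (-2.37 ± 0.81, adjusted p = 0.0368), with 3 passing when adjusted over the list alone. miR482/miR2118 did not pass in edgeR over all families (-1.41 ± 0.57, adjusted p = 0.053). It did when adjusted over the list alone, where it was the only family tested. The organ and meristem, silencing machinery and monocot lists had 0 calls in 5, 1 and 1 tested families, also when adjusted over the list alone, with 1, 0 and 0 families at an unadjusted p under 0.05 in edgeR. miR2275 was below the filter, with 5 reads over the 6 female libraries. With size as a covariate miR393 (log2 1.37) and tasiR-ARF (log2 -0.99) both had an adjusted p of 0.103, miR156 was at -0.56 (adjusted p = 0.0469) with exact matching, and tasiR-ARF and miR398 lost their calls without the 2.0, 2.8, 3.5 or 4.5 mm female pistils or the 1.5 mm male pistils (log2 -0.78 and -1.40 without the last), as tasiR-ARF did without the 0.5 mm male pistils (-0.81). The calls of miR156 and miR319 were lost without the 2.0 mm female pistils (adjusted p = 0.0609 and 0.0543), and that of miR156 also without the 2.8 mm female or 1.5 mm male pistils (both adjusted p = 0.0719), while miR482/miR2118 passed with DESeq2 (log2 -1.44, adjusted p = 0.0264). The count was 13 with DESeq2, with TMM and with no filter, 2 without the 2.0 mm and 3 without the 2.8 mm female pistils, and 11 without the 1.8 mm male pistils.

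Among 3520 abundant tags, 941 differed between female and male pistils, 575 higher and 366 lower in female pistils. The 24-nt tags numbered 220 higher and 85 lower of 1209. The 24-nt tag ACCGAGGTTCAGACTGGAGCAATC was at 65.1 ± 71.1 CPM in female pistils, while the 5 male pistil libraries together held 4 reads of it. TCCCGCCTTGCATCAACTGAAT (log2 4.37 ± 1.00) and CACTTGCAGACCGAGACACACAGA (log2 4.07 ± 0.74) were higher as well. The lower tags were CCGGAGGTAGGGTCCAGCGGCT, at 72.1 ± 47.3 against 253 ± 94.9 CPM (log2 -1.79 ± 0.40), TCTCGGACCAGGCTTCATTCT (log2 -1.66 ± 0.21) and CCGCTCACGCCCGGTCGTACT (log2 -1.63 ± 0.31). With size as a covariate 74 tags passed, of which 72 were among the 941, and TCCCGCCTTGCATCAACTGAAT (log2 2.04 ± 1.23), CCGCTCACGCCCGGTCGTACT (-1.39 ± 0.51) and CCGGAGGTAGGGTCCAGCGGCT (-1.02 ± 0.54) did not. Over the 941 tags the covariate kept the direction of 936, with a median 0.731 of the log2 difference, while the median SE went from 0.294 to 0.422. With a filter of 5 CPM the count was 3286. The lower tag at log2 -1.66 holds, after its first bases, the start of the main miR166 tag. It is therefore a variant of a listed family with a shifted start, not an unlisted small RNA. It also differs only in its last base from a far more abundant 21-nt tag. Whether it is a misread of that tag was not tested.

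Several families were lower in floral organs than in vegetative tissue. miR398 was at 2.85 ± 3.38 RPM in the reproductive libraries (SD, n = 16) and 96.2 ± 134 RPM in the vegetative libraries (SD, n = 3), and miR408, which targets copper protein transcripts, at 2.45 ± 2.09 against 23.2 ± 16.2 RPM. miR535 was also lower, at 10.8 ± 6.78 against 64.3 ± 28 RPM. In the other direction, miR5179 was at 20.1 ± 25.4 RPM in reproductive libraries, while the 3 vegetative libraries together held 8 reads, and miR390 was at 12.7 ± 10.1 against 1.94 ± 1.93 RPM.

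In edgeR, 7 of 24 tested families passed, 2 higher and 5 lower in reproductive tissue. Of 5 tested nutrient and stress families, miR398 (log2 -5.08 ± 0.89, adjusted p = 0.000222), miR408 (-3.24 ± 0.60, adjusted p = 0.000222) and miR528 (-2.77 ± 0.77, adjusted p = 0.00722) fell, with 4 passing when adjusted over the list alone. All 16 reproductive libraries lay below the 3 vegetative libraries for these families and for miR535 (-2.58 ± 0.52, adjusted p = 0.000405), the 1 call among 5 phase and flower families. miR396, which targets growth-regulating factor transcripts, fell (-1.78 ± 0.57, adjusted p = 0.0207) among 5 organ and meristem families, with 3 passing when adjusted over the list alone. miR5179, of the monocot list, rose (7.86 ± 2.13, adjusted p = 0.00722), and so did miR390 (2.71 ± 0.92, adjusted p = 0.0259) of the tasiRNA list, whose other member tasiR-ARF had a log2 difference of -0.05 ± 0.83 (adjusted p = 0.95). The auxin, silencing machinery and phasiRNA trigger lists had 0 calls in 3, 1 and 2 tested families, also when adjusted over the list alone, with 1, 0 and 1 families at an unadjusted p under 0.05 in edgeR. miR482/miR2118 had a log2 difference of 1.46 ± 0.77 (adjusted p = 0.134), and passed with DESeq2 (1.83, adjusted p = 0.0137). No read of miR2275 was found in the vegetative libraries, where a count of 0 allows up to 0.0999, 0.0887 and 0.097 RPM, and its adjusted p was 0.0789. The count was 13 with DESeq2 or with anthers as the only floral organ and 4 without any 1 of the vegetative libraries. miR396 lost its call with anthers as the only floral organ (log2 -0.90, adjusted p = 0.173) and without any 1 of the vegetative libraries. miR390 lost its call without the old spear or the shoot of a young plant, and miR398 without the cladophylls (log2 -2.75, adjusted p = 0.0516).

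Among 4448 abundant tags, 2029 differed between reproductive and vegetative tissue, 1017 higher and 1012 lower in reproductive tissue. The direction depended on length: 737 of 1524 tags of 24 nt were higher and 209 lower, against 114 higher and 324 lower of 1067 tags of 21 nt. The 24-nt tag AAGTCAAGATGACTGAACTGTCCT was at 76.5 ± 33.7 CPM in reproductive and 0.102 ± 0.103 CPM in vegetative libraries (log2 9.07 ± 0.89). The 21-nt tags ATCGCAGATTATGGATATCTG (log2 8.45 ± 1.50) and TCTACCATGACCTCTGAAGCA (log2 8.45 ± 1.53) were also higher. TTGTAGAAATTCCTGGATCAAC fell from 312 ± 135 CPM in vegetative to 2.98 ± 3.10 CPM in reproductive libraries (log2 -7.30 ± 0.63), with GGAGAGATGGCTGAGTGGAC (log2 -5.99 ± 0.41) and AGTTACTAATTCATGGTCTGGC (log2 -5.84 ± 0.75). The last tag named had 4822 reads over the vegetative libraries. It differs at a single base from a far more abundant 22-nt tag. That tag had 1158620 reads in cladophylls, 504438 in the old spear and 876780 in the shoot of a young plant. Whether the named tag is a misread of it was not tested, so its change may not be that of a separate small RNA. Without TMM scaling, which moved the median tag by 0.483 on the log2 scale, 1343 tags were higher and 318 lower. With a filter of 5 CPM the count was 7864.

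Exact matches to the core of 5.8S rRNA, the only rRNA sequence used, made up 1.11% ± 0.269 of reads in reproductive and 1.07% ± 0.24 in vegetative libraries, and matches to 3 tRNAs 0.116% ± 0.0386 and 0.137% ± 0.0268. None of 6 exact permutation tests on these shares passed after adjustment, the lowest being tRNA in female against male pistils (p = 0.039, adjusted 0.234). These shares are lower bounds and no measure of RNA breakdown, since TACGACTCTTGGCAACGGATATCTTGG, which resembles the 5.8S reference without matching it, had 267302 reads in the 1.1 mm male pistils alone.

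Within organ series, several families changed with size. In anthers 4 of 21 tested families had a slope, with miR166 (2.25 ± 0.71 log2 per mm, adjusted p = 0.0126), which targets class III homeodomain-leucine zipper transcripts, miR396 (2.11 ± 0.55, adjusted p = 0.00303) and miR159 (1.51 ± 0.35, adjusted p = 0.00107) rising and miR168 (-1.40 ± 0.40, adjusted p = 0.00596), which targets ARGONAUTE1 transcripts, falling. In male pistils 10 of 21 had one. There miR398 (3.52 ± 0.88), miR399 (2.54 ± 0.47), miR5179 (1.96 ± 0.54), miR827 (1.52 ± 0.48), miR319 (1.44 ± 0.28), miR168 (1.17 ± 0.43) and miR396 (1.08 ± 0.24) rose, and miR167 (-3.11 ± 0.69), miR390 (-2.77 ± 0.65) and miR482/miR2118 (-2.60 ± 0.66) fell. In female pistils 2 of 20 rose, miR5179 (0.94 ± 0.23, adjusted p = 0.00171) and miR393 (0.50 ± 0.16, adjusted p = 0.0223). miR2275 had an anther slope of -5.18 per mm with an adjusted p of 0.405 in edgeR and of -5.94 with an adjusted p of 0.00264 in DESeq2. The anther count was 0 in edgeR without the 1.1 mm anthers (5 families at an unadjusted p under 0.05), 2 without the 0.7 mm anthers, 1 with TMM and 8 with DESeq2, and the male pistil count was 6 without the 1.8 mm library, where the slope of miR168 was 0.36 (adjusted p = 0.69). Single slopes were also lost for miR168 in anthers without the 1.8 or 2.0 mm library (adjusted p = 0.17 and 0.222) and in male pistils without the 0.5 or 0.7 mm library (0.132 and 0.0772). In male pistils the same held for miR827 without the 0.5, 1.5 or 1.8 mm library (0.0571, 0.0796 and 0.0604), miR5179 without the 0.7 or 1.8 mm library (0.0772 and 0.102), and miR168 (0.0751) and miR396 (0.107) with TMM. The female count was 0 without the 1.5, 2.0 or 4.2 mm pistils (3, 2 and 3 families at an unadjusted p under 0.05), 5 without the 4.5 mm pistils, and 1 with DESeq2 or with ranks of size. The female slope of miR393 lost its call with DESeq2 and with TMM. It ranged from 0.188 to 0.600 over these and the single omissions.

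**Figure D2:**
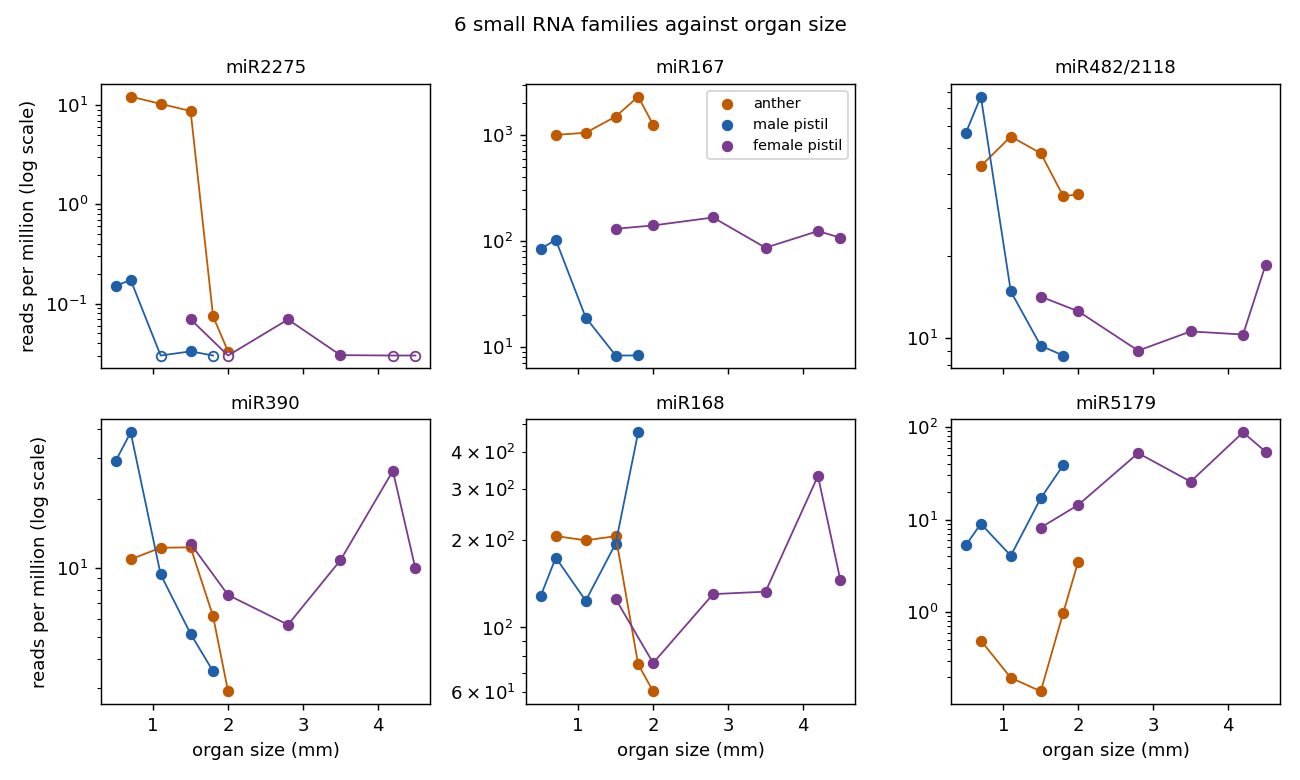
RPM (log axis) of 6 families against organ size in mm for anthers, male pistils and female pistils, with 1 point per library; open symbols mark 0 reads, drawn at 0.03. miR2275 lies at 8.72 to 12.2 RPM in anthers up to 1.5 mm and below 0.1 RPM in larger anthers.

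Whole buds and size-range anthers gave 1 library for each size range and no test. In buds with anthers under 0.5 mm and of 0.5 to 1.0 mm, miR2275 was at 3.21 and 4.25 RPM, and in the library labelled buds of 1.0 to 1.5 mm at 4.98 RPM. In the libraries labelled anthers of 0.5 to 1.0 mm and of 1.0 to 1.5 mm it was at 6.49 and 2.45 RPM. tasiR-ARF was at 79.1, 39.0 and 3.38 RPM in the bud libraries by rising size and at 11.7 and 108 RPM in the anther libraries. Across the 6 families that were lower in single-size anthers than in male pistils, the library labelled 1.0 to 1.5 mm buds lay below the library labelled 1.0 to 1.5 mm anthers in each. These 5 libraries also held 3.77 to 8.64% of a kit oligonucleotide that reached at most 251 reads in any of the other small RNA libraries.

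**Figure D3:**
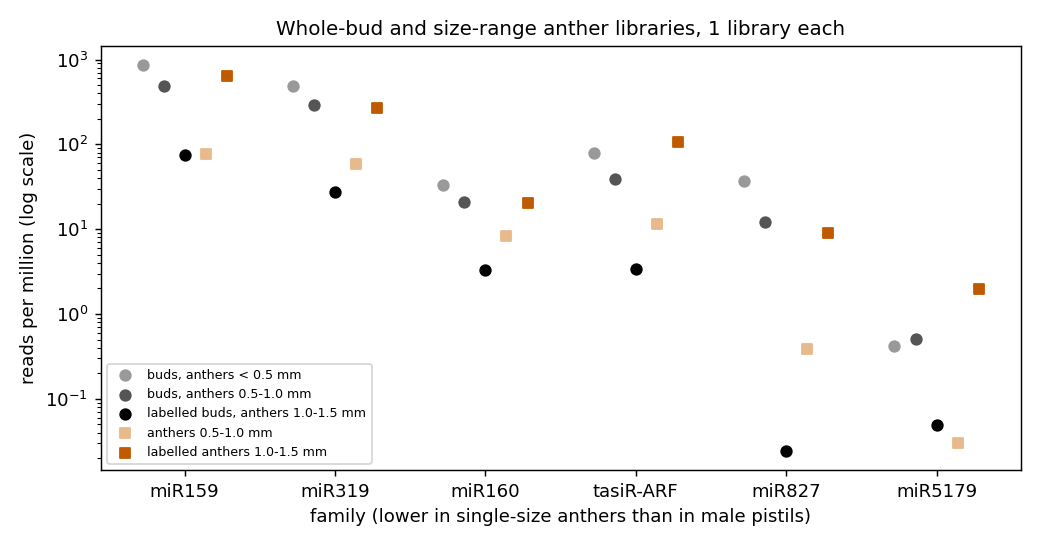
RPM (log axis) in the whole-bud and size-range anther libraries of the 6 families that were lower in single-size anthers than in male pistils, with 1 point per library. The library labelled 1.0 to 1.5 mm buds lies below the one labelled 1.0 to 1.5 mm anthers in all 6 families.

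The dsRNA libraries, from RNA of the 2 smaller bud ranges cut with RNase ONE or RNase V1, had 24-nt shares of 7.72 and 7.63% after RNase ONE and 9.38 and 9.09% after RNase V1. Of the 31 families, 28 had no read in any of them, miR2275 included (limits of 0.146 to 0.248 RPM), and the other 3 had at most 45 reads in a library.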

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

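Every test in this part was chosen or worded after the result it bears on had been seen.

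The count of changed families or tags was compared with 100 splits of the same libraries in each comparison. For anther against male pistil, 1 of 100 splits (the real one) gave as many as the 13 families, with a highest other of 1, and 1 of 100 gave as many as the 993 tags, with a highest other of 410. For female against male pistil, 2 of 100 splits gave as many as the 6 families, with a highest other of 6, and 1 of 100 as many as the 941 tags, with a highest other of 627. That last split exchanged the 1.5 mm female pistil with the 1.8 mm male pistil, so it kept most of the real grouping. For reproductive against vegetative tissue, 2 of 100 splits gave as many as the 7 families, with a highest other of 9 in a split that set the 1.1, 1.5 and 1.8 mm anthers apart, and 1 of 100 as many as the 2029 tags, with a highest other of 254. An accident of the grouping is therefore unlikely for the counts that no other drawn split reached. For families in female against male pistils another split reached the same count, and in reproductive against vegetative tissue another split passed it. Those family counts alone do not set the real grouping apart, and the anthers form a second structure in the last comparison.

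The bud and anther libraries labelled 1.0 to 1.5 mm are the first pattern, since the bud library carried anther-like levels of the families low in anthers and the anther library bud-like levels. Exchanged labels, other floral tissue in the anther sample alone, and anthers filling most of the larger buds alone were each tested by 2 measures, the second taken up after the first had been seen. Neither the summed CPM of the 462 tags lower in anthers (labelled buds at 1.15 times the labelled anthers and 1.16 times the lower of the smaller buds, labelled anthers at 0.917 times the 0.5 to 1.0 mm anthers) nor the 156 of them that are 24 nt long (median log2 -0.86, labelled buds less labelled anthers) decides anything, since neither was higher in the smaller buds than in the 0.5 to 1.0 mm anthers, whose labels are not in question (0.913 times, median log2 -0.23). The 6 families were, but the pattern was seen in them, so they are no separate test of the other 2 causes. The labelled buds stood at a median 0.106 of the lower of the smaller buds (highest family 0.159). The labelled anthers stood at a median 8.79 times the 0.5 to 1.0 mm anthers (lowest family 2.43). In these families neither cause acting alone covers both departures. Exchanged labels and those 2 causes acting together stay open. The families that show the pattern cannot also test an exchange, and other values run both ways. As the labels say, the tags higher in anthers summed to 21430 CPM in the labelled buds and 26504 in the labelled anthers (22897 and 28779 in the smaller buds, 32464 in the 0.5 to 1.0 mm anthers). Against the labels, 5 of the 7 families higher in anthers stood higher in the labelled buds and only miR169 and miR396 in the labelled anthers. The 675 24-nt tags of the smaller anthers, chosen without these libraries and described under the other observations, also ran against the labels. They summed to 366 RPM in the labelled buds and 70.8 RPM in the labelled anthers. The smaller buds gave 51.3 and 119 RPM, and the 0.5 to 1.0 mm anthers 254 RPM. Each of these values rests on 1 library.

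The fall of miR2275 between anthers of 1.5 and 1.8 mm is the second pattern. Library depth was excluded, since the 1.8 and 2.0 mm libraries held 5 reads (upper bound 11.7) where the rate of the 1.5 mm library gave 734. A few tags taking most of the reads were excluded as well, since the ratio of larger to smaller anthers was 0.00558 without the 10 most abundant tags. Pistil or vegetative tissue in the larger anthers was excluded as the whole cause, since their higher tasiR-ARF level was 0.236 of the lowest pistil or vegetative library. Other organs had no library of their own here, so their tissue was not excluded. A change with anther stage may account for it, as a hypothesis that no second library of any size can test here.

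Single libraries stood far from the rest of their group in 5 of 65 sets of values, where chance gives about 3.25. They were miR5179 in the 2.0 mm anthers (3.52 RPM), miR168 in the 1.8 mm male pistils (468 RPM) and in the 4.2 mm female pistils (331 RPM), miR390 in the 4.2 mm female pistils (26.4 RPM) and tasiR-ARF in the 4.5 mm female pistils (116 RPM).

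The change per mm differed between anthers and male pistils in a joint edgeR fit for 7 families. The anther slope exceeded the male pistil slope by 3.79 ± 0.58 for miR167 (adjusted p = 1.03e-05), 3.00 ± 0.81 for miR166, 2.96 ± 0.39 for miR172, 2.18 ± 0.68 for miR482/miR2118 and 1.52 ± 0.44 for miR159. The difference was -3.12 ± 0.88 for miR399 and -2.58 ± 0.62 for miR168. For miR172 the male pistil libraries held only 10, 6, 4, 2 and 2 reads by rising size, below the filter for a male pistil slope. Its anther slope alone did not pass in edgeR (1.37 ± 0.99, adjusted p = 0.40). Each SE here was derived from the F statistic of the test. With so few reads, a joint SE of 0.39, below the 0.99 of the anther slope alone, is too small. The call of miR172 among the 7 is therefore not relied on.

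A signal outside the main measurement was the kit oligonucleotide GAATTCCACCACGTTCCCGTGG. It made up 5.40, 8.64 and 3.77% of reads in the bud libraries by rising size, and 5.32 and 5.23% in the size-range anther libraries.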

How the results depend on the processing

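Adding the 0.5 to 1.0 mm size-range anthers alone was chosen after seeing the data, as was the reading of the planned size covariate as a test of organ size, and all other alternatives were fixed before the data were examined. Of 136 alternatives for counts of calls, 108 stayed within 1.5 times the reported count. Of 606 for named families, 556 kept direction and side of the threshold, 27 lost the call, 11 gained one and 12 reversed. For slopes the numbers were 85 of 115 kept, 29 lost and 1 gained, for named tags 312 of 315 kept, and for shares 104 of 112. The cause of each change was not tested.

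Shares, in points, moved as follows. Female minus male pistil at 24 nt was -0.743 with sizes of 1.5 to 2.0 mm only. Reproductive minus vegetative was 2.35 (24 nt) and -0.654 (21 nt) over distinct tags. At 21 nt, anther minus male pistil was -0.0404 without the 10 most abundant tags and ranged from -0.955 to 1.58 leaving out single libraries, below 0 without the 1.8 or 2.0 mm anthers (-0.0203). Female minus male pistil at 21 nt was -2.30 over reads of 20 to 24 nt (exact permutation p = 0.0325) and 0.263 without the 10 most abundant tags.

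Counts of families were 13 with DESeq2, with no filter and with TMM for female against male pistil (2 to 11 leaving out single libraries), and 13 with DESeq2 or anthers alone for reproductive against vegetative (4 to 8). TMM shifted family values in the latter by a median of 0.449 on the log2 scale. Counts of tags with a 5 CPM filter were 4340, 3286 and 7864 in the order of the report, and leaving out single libraries gave 590 to 1118, 634 to 1139 and 1448 to 2068. With size as a covariate 74 tags passed between female and male pistils. For the 869 of the 941 tags that did not, the calls ended through a smaller median fold (log2 1.08 before and 0.76 after) and a larger median SE (0.288 and 0.415) together, so organ size and sex cannot be told apart for these. Families with a slope numbered 8 with DESeq2 and 1 with TMM in anthers (0 to 6), 6 to 11 in male pistils, and 1 with DESeq2 and 1 with ranks in female pistils (0 to 5), the ranges leaving out single libraries.

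Reversed families were miR396 in anthers (-0.018) and miR156 in female pistils (-0.561) with exact matching, and miR390 in female pistils without the 0.7 mm male pistils (0.0446, where leaving out single libraries gave -0.882 to 0.0446). tasiR-ARF in reproductive tissue, near 0 as reported, reversed with DESeq2 (0.47), with TMM (0.671) and over 7 single libraries left out (all single omissions -0.221 to 0.0747), and was -2.97 for anthers alone. With the size-range anthers added, 11 families and 822 tags passed, and 12 and 839 with the 0.5 to 1.0 mm library alone.

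With the series number as a replicate block, 14 families (13 shared) and 777 tags (729 shared) passed, and the exact sign-flip p was 0.63 for the 24-nt and 0.688 for the 21-nt share. The differences were 1.75 and 0.629 points, and miR482/miR2118 passed (0.93, adjusted p = 0.0491). The numbers did not pair the libraries: 2 of 5 correlations of same-numbered libraries exceeded 0.1, and 1 of 5 anther libraries correlated best with its own number.

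Loci of 24-nt phased tags, their slopes, reads and inverted repeats, with all their alternatives, were not run because no genome was used here. With 3 vegetative libraries, families changed 4-fold were recovered at 20% in simulated data, so families without a call there are not shown to be alike.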

Other observations

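The tests in this part were chosen after the result was seen, except that of 23-nt tags, which was worded before its result was seen.

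A set of 24-nt tags was read mainly in the smaller anthers. Of 115900 tags with at least 30 reads over anthers up to 1.5 mm, 675 had at most 0.1 of that number in the larger anthers and at most 0.05 in any other group. These tags were chosen for this pattern, so their levels in the choosing libraries (741, 879 and 650 RPM in anthers of 0.7, 1.1 and 1.5 mm, and 20.6 and 15.3 RPM at 1.8 and 2.0 mm) are no test of it. In the libraries that took no part in the choice, they summed to 51.3 and 119 RPM in the smaller buds and 254 RPM in the 0.5 to 1.0 mm anthers, where 146, 187 and 280 of the 675 were seen at all. The libraries labelled 1.0 to 1.5 mm gave 366 RPM for buds (554 tags seen) and 70.8 RPM for anthers (270 seen). The most abundant were ATAACTGTTGACCATGTCGCGCCT, with 7271 reads in the smaller and 70 in the larger anthers, and AATAGAACCAGAACATAAAAACCC, with 6853 and 82.

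A hypothesis was that 24-nt tags lie end to end in the dsRNA reads, as stepwise cutting of a double-stranded precursor would leave them. Only dsRNA reads of 51 nt were searched, pooled over the RNase ONE and RNase V1 libraries. The reads left by each enzyme were not told apart, and whether they came from double strands was not tested. Among 24-nt tags with at least 20 reads, 128 distinct pairs of tags started 24 nt apart in these reads. At 23 nt there were 76 pairs and at 25 nt 85, a ratio of 1.59 (exact binomial p = 6.92e-05). The ratio was 2.23 for tags with at least 100 reads. Against pairing at a tag's own length whatever that length, 23-nt tags gave 0.953 (exact binomial p = 0.631), from 41 pairs at 23 nt. That explanation is not excluded, since tags of 21 nt gave 1.15 (exact binomial p = 0.0882) and, with at least 100 reads, 1.52 (exact binomial p = 0.029). The 22-nt tags gave 0.914. The excess may reflect stepwise cutting, which these values do not tell apart from pairing at other lengths as well. Pairs from repeated sequence are not independent of each other, which makes these p-values too small.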
